A study of Bos taurus with 6 samples.

How the data were processed

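Gene expression was measured in cumulus cells of Holstein dairy cows on 2-colour microarrays. Per the labels, 6 cows were stimulated with follicle-stimulating hormone (FSH) for 3 days, and cumulus cells were recovered 68 h after the last FSH injection. In the treated condition, cetrorelix was given at 12 mg per day for 5 days, from day 2 of FSH until recovery. Cetrorelix blocks the receptor for gonadotropin-releasing hormone (GnRH) and so lowers the secretion of luteinizing hormone (LH). The labels call it an agonist, whereas it is known as an antagonist. The control cells had FSH and its withdrawal without cetrorelix.

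Per the labels' protocols, RNA was extracted with a small-sample column kit, amplified, and labelled chemically with Cy3 or Cy5 at the guanines of the amplified RNA. Each of 6 arrays held both conditions. On 3 arrays the cetrorelix RNA was in Cy5 and the control RNA in Cy3, and on the other 3 the dyes were swapped. The series' design text states 3 biological replicates per treatment on a dye swap, so the 2 arrays with the same replicate number were taken as a dye swap of the same extracts and counted as 1 replicate. The arrays of one dye orientation shared a slide and those of the other orientation shared another, so slide and dye orientation cannot be told apart. The labels do not say which cows or how many cows stand behind a replicate. The p-values of single probes rest on the spread between the 3 replicates, with variances moderated across all tested probes, and not on a known number of cows.

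The deposited scanner tables hold, per the file headers, the raw median intensity and the median local background intensity of each spot for the Cy5 and the Cy3 laser, with no background correction. The image analysis program is not given in the sources used here. The authors also deposited a normalized table and a table of series values, both on a log2 scale. Set against the scanner intensities, the normalized table ran as Cy5 over Cy3, and the series values were the same numbers turned to cetrorelix over control. The largest gap after turning was 5e-06. The submitters' processing notes name limma, with no version and no settings, so the authors' background correction and normalization are not given in the sources used here. The authors' log2 values correlated with the ratios computed here at r = 0.992, 0.987 and 0.865 across probes on the arrays of replicates 1, 2 and 3 with cetrorelix in Cy5, and at 0.798, 0.991 and 0.987 on those with cetrorelix in Cy3. The column medians of the series values were 0.01, -0.03, 0.01, -0.01, -0.01 and -0.02. Their centring therefore lay close to 0, and the method of centring is not given in the sources used here.

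Each array listed 45212 spots, of which 43794 were gene probes and 153 were negative controls. Spots that the image analysis marked to be ignored (between 36 and 94 per array) were set to missing. Background was corrected with normexp (offset 50), the log2 ratio was normalized within each array by loess with control spots at weight 0, and no step was applied between arrays. A channel counted as above background where its intensity exceeded the 95th percentile of the negative controls of that array and channel. Probes above background on at least 3 arrays in the cetrorelix channel or on at least 3 in the control channel were kept (32358), and 32125 of them had a value on every array, while 233 were left out for a marked spot. Arrays have no read depth, and the number of arrays limits the precision. The share of probes above background ranged from 40.9% to 70.9% in the cetrorelix channel and from 54.8% to 69.7% in the control channel, and the lowest share belonged to replicate 2 with cetrorelix in Cy5.

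Ratios were turned to cetrorelix over control, the 2 arrays of a replicate were averaged, and the 3 averages were tested against 0 with limma (lmFit and eBayes, limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all tested probes. A dye effect of the same size on the 2 arrays of a replicate cancels in the average. The SD of the log2 ratio across tested probes differed within replicates. It was 0.54 with cetrorelix in Cy5 and 0.32 with cetrorelix in Cy3 for replicate 1. For replicate 2 it was 0.58 and 0.66, and for replicate 3 it was 0.32 and 0.51. Whether the size of the dye effect differed likewise was not tested. Errors are the SD of the 3 replicate averages. A gene with several probes was read from its probe of highest mean log2 intensity. Values of other probes are given below for some genes only. Symbols came from the platform annotation, in which 21790 probes had exactly 1 symbol, 0 had several and 22004 were not listed with one. Of those symbols, 20068 matched a current symbol of the ARS-UCD2.0 gene table, 1644 matched through a synonym and 78 were kept as listed. This left 12398 tested genes, 2964 of them with more than 1 tested probe. No coordinates were used.

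Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all 23 lists (18 pathways and 5 sets of markers of other cell types), with camera at an estimated correlation and fry beside it. Camera compares a list with all other genes, so its p-values also depend on the spread across genes and on the correlation used. The lists, the tests, the alternatives and the rule for naming genes were chosen before the data were examined. The rule took, per direction, the 12 genes of largest change among those past adjusted p of 0.05 with the same sign on all 6 arrays, filled with the genes of lowest p that changed at least 1.5-fold with the same sign on all 6 arrays. It added up to 4 members of each list by lowest p, and the genes LHCGR, FSHR, CYP19A1, STAR, PTGS2, HAS2, PTX3, TNFAIP6, AREG, EREG, PGR and INHBA where measured. EREG had no probe under that symbol. A further item is not reported here.

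The pairing by replicate number comes from the stated dye swap. In log2 intensities averaged per RNA, the deviations of the cetrorelix and control RNA of a number from their group means correlated across probes at 0.26, 0.00 and 0.13 for replicates 1, 2 and 3. After turning, the consensus correlation within replicate numbers was 0.25. Alternatives were no background correction, plain subtraction, median centring without loess, Aquantile between arrays, no filter and a stricter filter on dim probes, the authors' log2 values, 6 arrays with the replicate number as a block, 6 arrays taken as independent, 3 against 3 without the pairing, a variance trend with robust variances, each slide alone, each replicate left out, and, for lists and genes, the mean of all probes of a gene.

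The procedure was tested on simulated data, in 3 runs of 32125 tested probes. The simulation was changed 4 times after the recovery had been seen, because the simulated spread came out larger than the spread put in. The recovery depended on the version: of 201 probes changed 3-fold, versions 1 to 5 recovered 0, 0, 19, 150 and 150 at adjusted p of 0.05. Versions 1 to 3 simulated only the tested probes, while versions 4 and 5 simulated all probes. The recovered share is therefore no firm measure of what the arrays could detect. In version 5, of 201 probes changed 2-fold, 5 passed, and of 201 changed 1.5-fold, 0 passed, although 147 of these had an unadjusted p under 0.05. Among 95712 unchanged probes 7 passed. A shift of -0.5 placed on a list of 20 genes was found by camera in all 3 runs, and 4 of 150 unshifted lists had an unadjusted p under 0.05. Replicate noise was drawn independently for each simulated probe, whereas the real cholesterol biosynthesis list had an estimated inter-gene correlation of 0.155. These counts therefore do not measure the error of camera on the real lists.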

Results

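Cumulus cells, the somatic cells that surround the oocyte in the follicle, were compared between cetrorelix treatment and control, both after FSH stimulation and 68 h of FSH withdrawal. Cetrorelix is used to suppress LH secretion, but the values used here hold no LH measurement. The labels do not say which cows stand behind each condition of a replicate. The comparison addresses how cetrorelix treatment acts on cumulus gene expression during FSH withdrawal. An effect of lower LH cannot be told apart from other effects of cetrorelix. There were 3 replicates per condition on 6 arrays, each replicate measured on 2 arrays with swapped dyes. All log2 ratios are cetrorelix over control, and each error is the SD over the 3 replicates. The median raw probe intensity lay between 179 and 226 in the Cy5 channel and between 220 and 270 in the Cy3 channel of the 6 arrays.

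Few transcripts passed the test. MRPL57, a protein of the mitochondrial ribosome, rose 3.35-fold after cetrorelix (log2 ratio 1.74 ± 0.38, SD, n = 3, limma adjusted p = 0.0398) and was higher on 6 of 6 arrays. The 3 other probes that passed rose to log2 ratios of 2.08 ± 0.23, 1.95 ± 0.21 and 2.06 ± 0.48 (adjusted p = 0.0101, 0.0101 and 0.0314), were higher on 6 of 6 arrays, and carry no gene symbol in the annotation used. In all, 4 probes were higher and 0 were lower at adjusted p under 0.05 by limma, of 32125 tested.

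At an unadjusted p under 0.05 there were 3569 probes, where chance alone gives 1606, of which 1698 were higher and 1871 lower after cetrorelix. With at least a 1.5-fold change added, 793 probes were higher and 662 lower (54.5% higher). Under median centring without loess these counts were 520 and 1109 (31.9% higher), so the balance of directions depended on that step. With the replicate number as a random block over all 6 arrays, 453 probes were higher and 315 lower at adjusted p under 0.05. Without replicate 1, 0 probes passed, and MRPL57 had adjusted p = 0.419. In a fit on the mean of all probes of each gene, MRPL57 had a limma adjusted p of 0.0880. MRPL57 has 1 tested probe, so its log2 ratio stayed at 1.74 in that fit.

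Next after MRPL57 came the genes of lowest p among those higher by at least 1.5-fold with the same sign on all 6 arrays. They did not pass, with adjusted p between 0.0653 and 0.0833. Those of regulatory function were JUN, a subunit of the AP-1 transcription factor, at a log2 ratio of 1.23 ± 0.09, FOSB, another AP-1 subunit, at 1.42 ± 0.44, GADD45A, a growth arrest and DNA damage gene, at 1.50 ± 0.51, MED15, a subunit of the Mediator complex, at 1.33 ± 0.35, and USP22, a histone deubiquitinase, at 1.33 ± 0.32. GADD45A had a second probe at -0.02, so its probes differed. PXDC1 lay at 1.30 ± 0.11, PPP1R14A, an inhibitor of myosin phosphatase, at 1.28 ± 0.13 with a second probe at 0.39, the tetraspanin CD151 at 1.34 ± 0.37, NUMA1, a mitotic spindle protein, at 1.17 ± 0.16, the decapping enzyme subunit DCP1B at 1.07 ± 0.09 and MAPK8IP3, a scaffold of JNK signalling, at 1.03 ± 0.12.

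Among genes lower after cetrorelix none passed. The 12 of lowest p among those changed at least 1.5-fold with the same sign on all 6 arrays had adjusted p between 0.0794 and 0.0833. The retromer subunit VPS29 lay at a log2 ratio of -1.23 ± 0.17, with a second probe at -0.21, and the glutathione transferase GSTM3 at -1.22 ± 0.37. Genes of mitochondrial energy metabolism were COX7A2, a subunit of cytochrome c oxidase, at -0.996 ± 0.256 and IDH3A, a subunit of isocitrate dehydrogenase, at -0.98 ± 0.25. Chromatin and DNA repair genes were YEATS4 at -1.11 ± 0.39, RBBP8 at -1.06 ± 0.37 and RBBP4 at -1.02 ± 0.34. The others were FDPS, which makes farnesyl diphosphate in the sterol pathway, at -1.08 ± 0.34, CCDC47 at -1.05 ± 0.34, the cadherin FAT1 at -1.04 ± 0.24, TMEM156 at -1.02 ± 0.35 and the calcium-binding protein SRI at -1.004 ± 0.304.

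**Figure D1:**
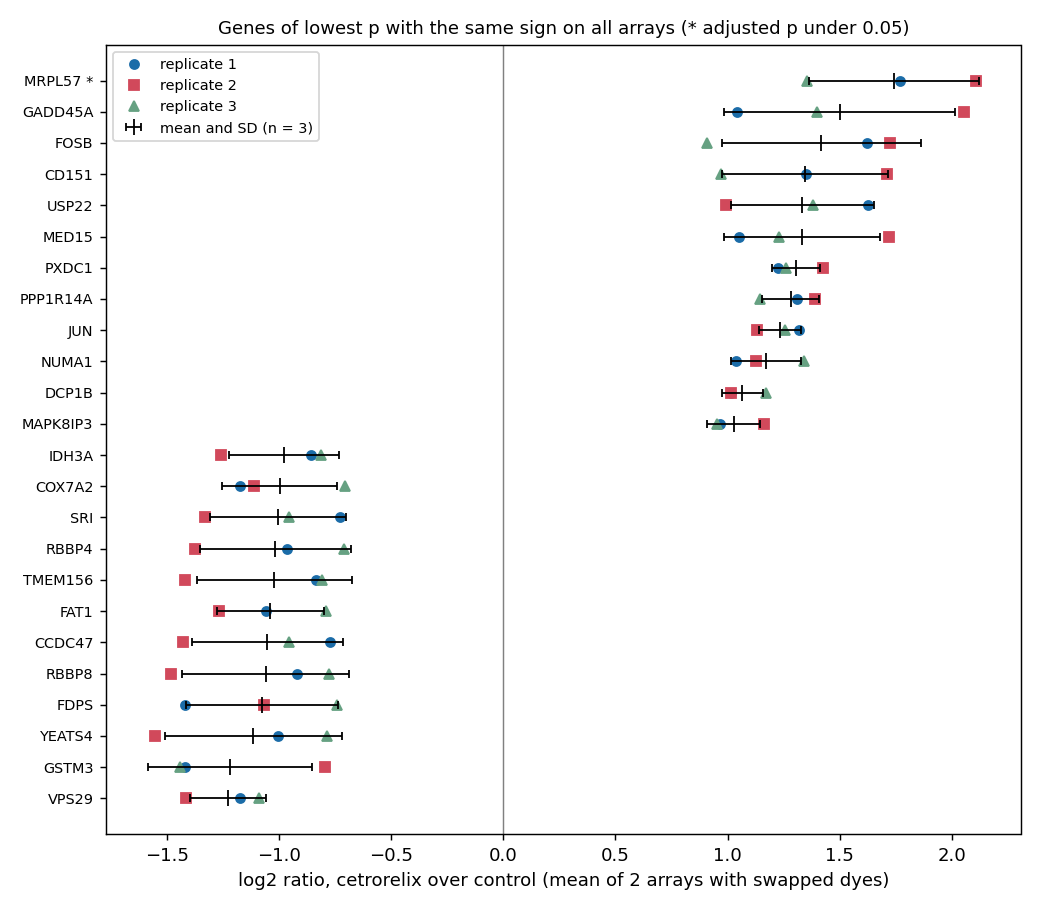
Log2 ratio of cetrorelix over control (horizontal axis) for the 12 genes of lowest p in each direction (vertical axis), with 1 symbol per replicate and the mean with its SD in black. MRPL57 (1.74), marked with a star, is the only one of these genes with adjusted p under 0.05.

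Cholesterol biosynthesis was the only list past camera's threshold. Of its 20 measured genes, 14 lay below 0 and 6 above, with a median log2 ratio of -0.19, and the medians of the 3 replicates were -0.28, -0.28 and -0.11. The list was lower than other genes by limma's camera (adjusted p = 0.0112), which was lost with an estimated correlation (adjusted p = 0.806 with an estimated correlation). By fry, which tests the list on its own, the adjusted p was 0.454. At an unadjusted p under 0.05, 9 members were lower and 1 was higher, and 0 passed over all genes, while 9 lower and 0 higher passed when adjusted over the list alone. FDPS had a log2 ratio of -1.08 ± 0.34, the sterol C4-demethylation enzymes NSDHL and MSMO1 had -0.89 ± 0.53 and -1.46 ± 1.20, and the sterol 14-demethylase CYP51A1 had -0.70 ± 0.35. The 4 probes of MSMO1 ranged from -1.82 to -0.01 and those of FDPS from -1.08 to -0.31. NSDHL had a second probe at -0.18, and the 3 probes of CYP51A1 ranged from -0.70 to -0.27. The median was -0.14 on the slide with cetrorelix in Cy5 and -0.33 on the slide with cetrorelix in Cy3. Without replicate 1 the adjusted p was 0.105, and with the mean of all probes of a gene it was 0.0794.

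No other list passed camera at adjusted p under 0.05, and no list passed with an estimated correlation or by fry. Genes known to be driven by LH and by EGF-like factors in the expanding cumulus did not pass as a group (17 measured, median 0.01, adjusted p = 0.769). In that list, 2 were higher and 1 lower at unadjusted p, with 0 passing over all genes and 1 higher adjusted over the list alone. The proteoglycan VCAN lay at a log2 ratio of 1.38 ± 1.02 and the protease ADAMTS1 at 0.56 ± 0.31, BTC, an EGF-like factor, lay at -0.42 ± 0.43, and the progesterone receptor PGR at -0.36 ± 0.49. The 3 probes of BTC ranged from -0.42 to 0.14. The expansion genes HAS2 (-0.02 ± 0.20), PTGS2 (-0.06 ± 0.24), PTX3 (0.04 ± 0.18), TNFAIP6 (0.15 ± 0.03) and AREG (-0.15 ± 0.23) were dim. HAS2 was above background on 2 of 6 arrays in cetrorelix cells and 3 of 6 in controls, and PTGS2 on 1 and 3. PTX3 was above background on 4 and 4, TNFAIP6 on 3 and 3, and AREG on 4 and 6.

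The steroidogenesis and luteinisation list did not pass as a group (16 measured, median 0.06, mean -0.03, adjusted p = 0.910), and its median and mean differed in sign. At unadjusted p, 1 member was higher and 4 were lower, 0 passed over all genes, and 1 higher and 3 lower passed adjusted over the list alone. CYP11A1, the first enzyme of steroid synthesis, had a log2 ratio of 1.01 ± 0.85. Its electron donor FDX1 had -0.55 ± 0.33, and HSD17B7 had -0.65 ± 0.50. NSDHL and HSD17B7 are among the genes in both this list and the cholesterol list. The cholesterol transporter STAR had 0.10 ± 0.30 and was dim. It was above background on 5 of 6 arrays in cetrorelix cells and 4 of 6 in controls, and had the same sign on 3 of 6.

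The list of FSH-dependent granulosa and cumulus genes (21 measured) had a median of -0.06 and a mean of 0.08, and camera placed it upward without passing (adjusted p = 0.862). At unadjusted p, 3 members were higher and 1 was lower, 0 passed over all genes, and 3 higher and 0 lower passed adjusted over the list alone. Those were the transcription factor GATA4 at a log2 ratio of 1.07 ± 0.41, the inhibin subunit INHA at 0.68 ± 0.05 and anti-Müllerian hormone, AMH, at 1.43 ± 1.23, each higher on 6 of 6 arrays. BMPR1B, which is also in the TGF-beta and BMP list, lay at -0.39 ± 0.06. The FSH receptor FSHR lay at -0.37 ± 0.37, aromatase CYP19A1 at -0.24 ± 0.66 and the inhibin subunit INHBA at -0.33 ± 0.29, with opposite signs on the 2 slides. The LH receptor LHCGR was not well above background.

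The immediate early list (24 measured) had a median of 0.04 and a mean of 0.17, without passing (adjusted p = 0.0894, and 0.853 with an estimated correlation). At unadjusted p, 8 members were higher and 3 lower, 0 passed over all genes, and 8 higher and 2 lower passed adjusted over the list alone. Of 7 AP-1 subunits, FOSL1 from outside the list included, 5 were higher and 1, FOS, was lower at unadjusted p under 0.05. This grouping was made after the values were seen, so its counts are descriptive. JUN (1.23 ± 0.09), FOSB (1.42 ± 0.44) and JUND (1.42 ± 0.72) lay above 0 and FOS at -1.02 ± 0.73, with a second FOS probe at 0.02. With the replicate number as a block, camera called the list higher (adjusted p = 0.0437).

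Metabolic lists gave values on both sides of 0. Oxidative phosphorylation (31 measured, median -0.16, adjusted p = 0.0894) had 6 members lower and 0 higher at unadjusted p, 0 passing over all genes and 0 adjusted over the list alone. Its lowest p belonged to NDUFA2 (-0.49 ± 0.25), ATP5F1C (-0.53 ± 0.41), NDUFB8 (-0.39 ± 0.09) and NDUFA1 (-0.55 ± 0.58), and its replicate medians were -0.33, -0.27 and 0.18. ATP5F1C had a second probe at 0.06. NDUFB8 lay at -0.59, -0.74 and -1.07 with cetrorelix in Cy5 and at -0.06, -0.26 and 0.37 with cetrorelix in Cy3. Glycolysis and glucose uptake (17 measured, median 0.14, adjusted p = 0.0902) had 5 higher and 1 lower, 0 over all genes, and 4 higher adjusted over the list alone. In that list the lactate transporter SLC16A3 lay at 1.09 ± 0.46, the glucose transporter SLC2A1 at 0.86 ± 0.22 with a second probe at 0.04, the hexokinase HK1 at 0.61 ± 0.29 and the phosphofructokinase PFKL at 0.81 ± 0.59. Antioxidant and glutathione genes (23 measured, median -0.19, adjusted p = 0.0980) had 4 lower and 0 higher, 0 over all genes and 1 lower adjusted over the list alone, with superoxide dismutase SOD1 at -0.84 ± 0.46, TXNRD1 at -0.34 ± 0.10, GPX4 at -0.72 ± 0.94 and PRDX3 at -0.72 ± 0.96. Hypoxia and angiogenic factors (17 measured, median 0.17, adjusted p = 0.474) had 3 higher and 1 lower, 0 over all genes, and 1 higher and 1 lower adjusted over the list alone. VEGFA lay at 0.75 ± 0.28, BNIP3 at 0.46 ± 0.22, VEGFB at 0.43 ± 0.30 and VEGFC at -0.66 ± 0.36. VEGFA had a second probe at 0.29 and PRDX3 had one at -0.12. TXNRD1 lay at -0.42, -0.79 and -0.65 with cetrorelix in Cy5 and at -0.48, 0.23 and 0.10 with cetrorelix in Cy3.

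Cell cycle and DNA replication genes (30 measured) had a median of -0.20 with 23 below 0, without passing (adjusted p = 0.0894). At unadjusted p, 2 were higher and 3 lower, with 0 over all genes and 0 adjusted over the list alone, and the replication helicase subunits MCM7 (0.52 ± 0.32), MCM5 (0.67 ± 0.82) and MCM3 (-0.43 ± 0.38) went both ways, with the spindle protein NUSAP1 at -0.40 ± 0.24. NUSAP1 had a second probe at 0.05, and CLU of the apoptosis list had one at 0.22. Apoptosis and atresia genes (16 measured, median 0.05, adjusted p = 0.696) had 2 higher and 1 lower, 0 over all genes and 0 adjusted over the list alone, with BID at 0.70 ± 0.36, CLU at 0.58 ± 0.41, CASP6 at -0.38 ± 0.21 and FAS at 0.29 ± 0.31. Cytosolic ribosomal proteins (23 measured, median 0.11, adjusted p = 0.0894) had 6 higher and 1 lower, 0 over all genes and 3 higher adjusted over the list alone, with RPS18 at 0.94 ± 0.29, RPLP0 at 0.64 ± 0.09, RPL32 at 0.65 ± 0.18 and RPL8 at 0.75 ± 0.73. The median of the ribosomal list was 0.40 on the slide with cetrorelix in Cy5 and -0.17 on the other, so its direction differed by slide.

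Stress and signalling lists did not pass either. Interferon response genes (21 measured, median 0.15, adjusted p = 0.0902) had 3 higher and 0 lower at unadjusted p, 0 over all genes and 1 higher adjusted over the list alone. IRF7 lay at 1.85 ± 1.41, ISG15 at 1.50 ± 1.90, RSAD2 at 1.58 ± 2.33 and IRF1 at 0.28 ± 0.22. ISG15 was 2.28, 2.88 and -0.67 in the 3 replicates and RSAD2 was 1.93, 3.71 and -0.90, and without replicate 3 the list passed (adjusted p = 4.67e-05). With all replicates it had adjusted p = 0.853 with an estimated correlation and 0.769 by fry. The extracellular matrix list (22 measured, median 0.08, adjusted p = 0.0902) had 4 higher and 2 lower, 0 over all genes and 2 higher adjusted over the list alone, the basement membrane collagens COL4A1 (0.96 ± 0.64) and COL4A2 (0.97 ± 0.66), with MMP14 at 0.47 ± 0.31 and TIMP2 at -0.44 ± 0.22. Unfolded protein and amino acid stress genes (19 measured, median 0.01, adjusted p = 0.430) had 4 higher and 1 lower, 0 over all genes and 4 higher adjusted over the list alone. They were CHAC1 (0.92 ± 0.26), CREB3L2 (1.13 ± 1.02), PDIA3 (1.25 ± 1.23) and DDIT3 (0.47 ± 0.09). The 3 probes of DDIT3 ranged from -0.11 to 0.47. Heat shock proteins (11 measured, median -0.15, mean 0.05, adjusted p = 0.862) had 2 higher and 0 lower, 0 over all genes and 0 adjusted over the list alone, with HSPB1 at 0.81 ± 0.63, BAG3 at 0.64 ± 0.53, DNAJB1 at 0.43 ± 0.59 and HSPA4L at -0.40 ± 0.42. Inflammatory cytokine and NF-kB genes (15 measured, median 0.15, adjusted p = 0.323) had 0 higher and 0 lower at unadjusted p, and 0 by either adjustment, the list alone included. IL1A lay at -0.51 ± 0.85, CXCL2 at 0.27 ± 0.20, NFKB1 at 0.20 ± 0.06 and LIF at 0.20 ± 0.11. The TGF-beta and BMP list (20 measured, median -0.08, adjusted p = 0.831) had 1 higher and 2 lower, 0 over all genes and 0 adjusted over the list alone, with SMAD6 at 0.87 ± 0.83, ACVR1 at -0.49 ± 0.41 and BMPR2 at -0.49 ± 0.73. SMAD6, CHAC1 and CXCL2 each had opposite signs on the 2 slides, on 3 of 3 arrays of each. ISG15 had a second probe at 0.59 and ACVR1 had one at -0.17. The 3 probes of DNAJB1 ranged from 0.01 to 0.43 and those of BMPR2 from -0.49 to -0.10.

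Markers of other cell types that a cumulus preparation can hold did not pass as groups. Leukocyte markers (9 measured, median 0.03, adjusted p = 0.923), endothelial markers (9 measured, median -0.04, adjusted p = 0.910), oocyte markers (7 measured, median 0.06, adjusted p = 0.831) and erythrocyte markers (6 measured, median 0.12, adjusted p = 0.430) each had 0 members past an unadjusted p of 0.05 and 0 adjusted over the list alone. Theca and stromal markers (11 measured, median 0.01, camera adjusted p = 0.769) had 1, ACTA2, and 0 adjusted over the list alone. ACTA2 had a log2 ratio of 0.48 ± 0.16. It lay at -0.37, -0.12 and 0.17 on the arrays with cetrorelix in Cy5 and at 1.22, 1.43 and 0.52 on the others. The lowest p values belonged to AIF1 (-0.24 ± 0.15) and LAPTM5 (-0.16 ± 0.10) among leukocyte markers, and SELE (0.17 ± 0.10) and ROBO4 (0.16 ± 0.11) among endothelial markers. They belonged to DDX4 (-0.33 ± 0.34) and KPNA7 (0.23 ± 0.32) among oocyte markers, GYPC (0.37 ± 0.45) and AHSP (0.20 ± 0.13) among erythrocyte markers, and DES (0.21 ± 0.04) after ACTA2 among theca and stromal markers. LAPTM5 had a second probe at 0.11, and the 3 probes of KPNA7 ranged from -0.10 to 0.23. Camera placed leukocyte and endothelial markers upward without passing, and their means (-0.00373 and 0.00307) had the opposite sign to their medians. Several of these markers were dim, DDX4 being above background on 1 array in the cetrorelix channel and 3 in the control channel.

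**Figure D2:**
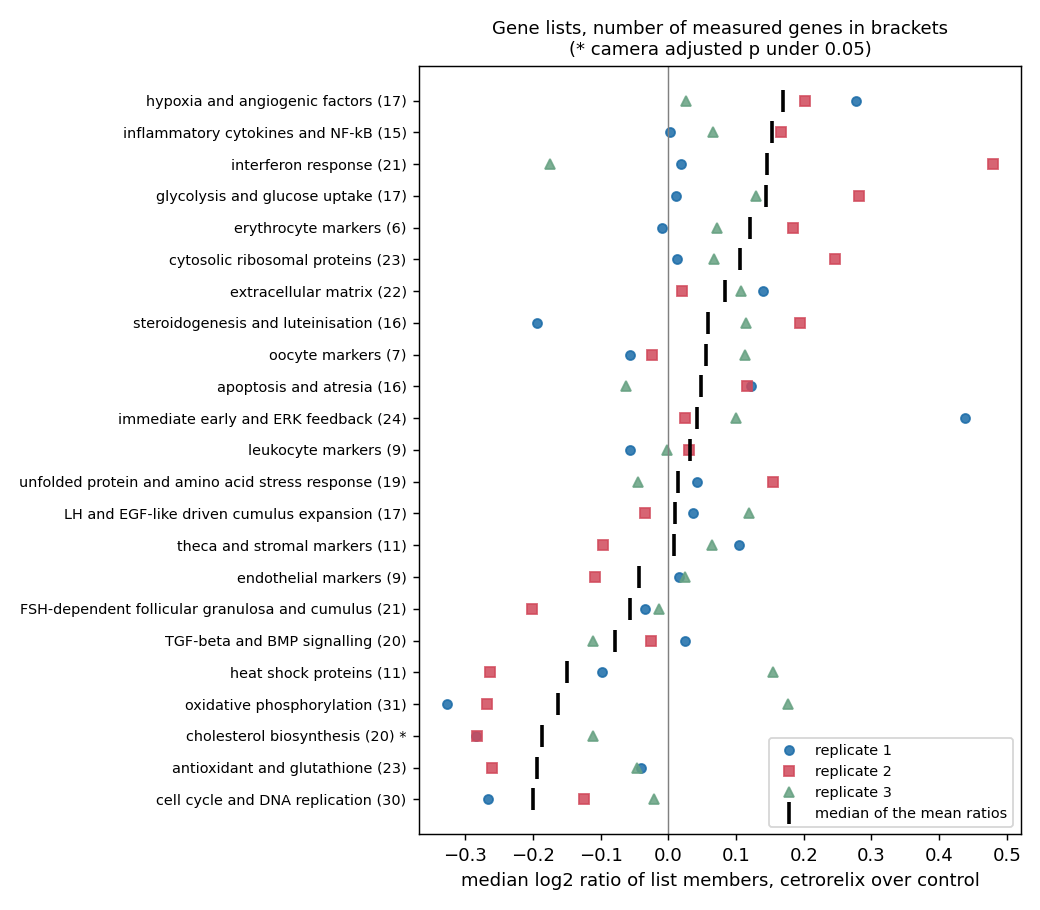
Median log2 ratio of cetrorelix over control (horizontal axis) for each gene list (vertical axis, number of measured genes in brackets), with 1 symbol per replicate and a black bar at the median over the mean ratios. The cholesterol biosynthesis list (median -0.19), marked with a star, is the only list past camera's adjusted p of 0.05.

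Across the 32125 probes, ratios of the averaged replicates correlated at 0.40 for replicates 1 and 2, 0.10 for 1 and 3 and 0.19 for 2 and 3. Between single arrays after turning, the mean correlation was 0.40 for arrays of the same slide, 0.07 for the arrays of 1 replicate with swapped dyes and -0.13 for arrays of other replicates with swapped dyes. These correlations are across probes, which are not independent replicates.

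**Figure D3:**
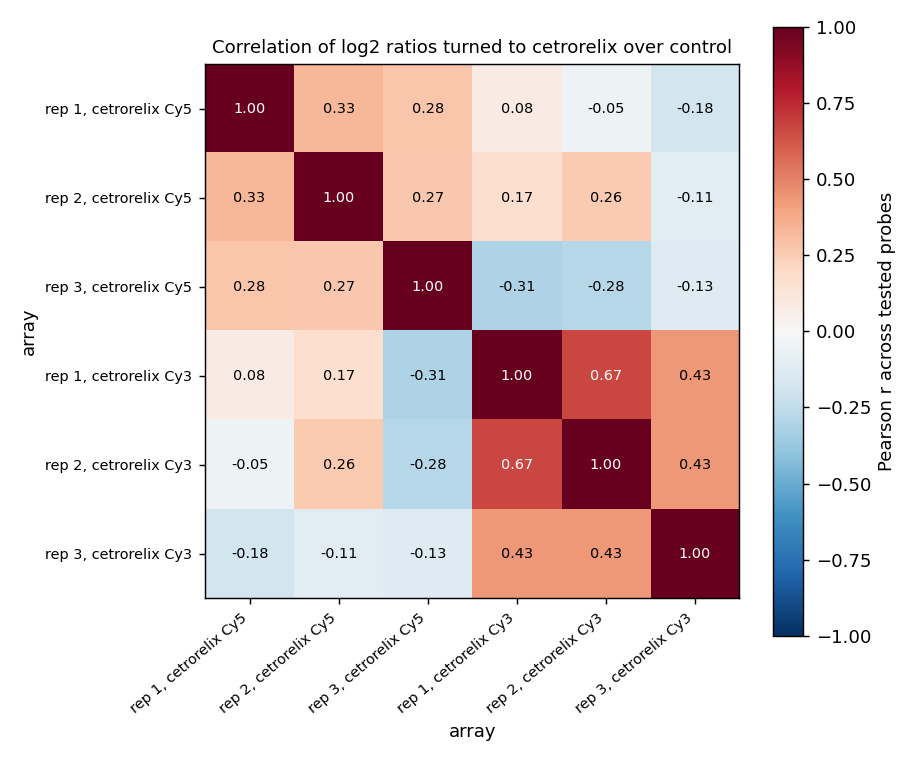
Pearson correlation across tested probes between the log2 ratios of the 6 arrays (both axes), turned to cetrorelix over control, with the value in each cell. Arrays of the same dye orientation (same slide) lie between 0.27 and 0.67, and arrays of opposite orientation between -0.31 and 0.26.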

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

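The limit for control spots and the look at single spike-in sequences were chosen only after the values were seen. Some kinds of control spot, which carry no bovine gene and enter no comparison, had ratios away from 0 after turning to cetrorelix over control. The mean log2 ratio was 1.46 ± 0.43 (SD, n = 3) for bright corner spots, 0.33 ± 0.32 for E1A spike-in spots and 0.35 ± 0.28 for the control spots named DCP, against 0.02 for negative control spots and a limit of 0.294 set from their spread. These 3 kinds exceeded that limit, which is what singled them out, while the dark corner, RC, ETG and eQC spots lay within 0.02 of 0. By replicate, E1A spots had 0.20, 0.69 and 0.10 and DCP spots 0.18, 0.68 and 0.19, so only replicate 2 exceeded the limit for these 2 kinds. The bright corner spots averaged 2.55 on the slide with cetrorelix in Cy5 and 0.36 on the other.

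The 10 E1A sequences, with 32 spots each, had mean log2 ratios from -1.47 to 3.22 in Cy5 over Cy3, and 6 of 10 kept the sign of that ratio on all arrays.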

How the results depend on the processing

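The threshold of 0.10 was chosen after seeing the data. Of counts at adjusted p under 0.05 (4 probes higher, 0 lower), plain subtraction of the background gave 152 and 35, no filter 7 higher, the stricter filter 15 higher, the authors' values 8 and 1, the replicate block 453 and 315, arrays as independent 595 and 500, 3 against 3 with no replicate block 1 higher, the variance trend 227 and 68, slide 1 alone 304 and 212, slide 2 alone 789 and 345, and adjusted p under 0.10 gave 153 and 55. Leaving out a replicate gave 0 to 707 higher and 0 to 547 lower. At unadjusted p and 1.5-fold (793 and 662), median centring gave 520 and 1109, the authors' values 1003 lower, slide 1 alone 1489 lower, slide 2 alone 2187 and 1457, and leaving out a replicate gave 487 to 1514 higher and 284 to 1535 lower. Taking 6 arrays as independent counts extracts more than once, a single slide keeps the dye effect, and the stricter filter tests fewer probes (11881). The replicate block instead takes the arrays of 1 number as correlated, at a consensus of 0.25. For the others, the cause was not tested.

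The median of the cholesterol list (-0.19) stayed below 0 in every alternative. It lost the call on slide 1 alone (-0.14), with an estimated correlation (-0.19), by fry (-0.19) and with the mean of all probes (-0.17). Leaving out a replicate gave -0.34 to -0.18, with the call lost without replicate 1. Other lists gained a call: oxidative phosphorylation lower with the authors' values (adjusted p = 0.0396), median centring (0.00132), no filter (0.0468) and without replicate 3 (0.00577), cell cycle lower with median centring (0.0154), no filter (0.0468) and without replicate 2 (0.00818), antioxidant genes lower with median centring (0.0203) and slide 1 alone (0.0251), ribosomal proteins higher on slide 1 alone (4.98e-05), interferon genes higher without replicate 3 (4.67e-05), and immediate early genes higher with the replicate block (0.0437), slide 1 alone (0.0303), without replicate 2 (0.00133) and without replicate 3 (0.0141). With all replicates and an estimated correlation, each of these lists had adjusted p of 0.806 or 0.853. Of 120 values of named genes, arrays as independent brought 52 past the threshold, the replicate block 50, slide 2 alone 45, the variance trend 35, plain subtraction 29, slide 1 alone 23, the stricter filter 8, the authors' values 5 and no filter 3. Leaving out a replicate brought 0 to 51. The stricter filter gave no value for 2 lists. No called result turned its sign. Aquantile acts on intensities and left every ratio as it was. All 4 probes passed in each alternative run on single probes except 3 against 3 (1 passed) and without replicate 1 (0 passed). With the mean of all probes of a gene, MRPL57 lost its call (adjusted p = 0.0880). It has 1 tested probe, and its log2 ratio of 1.74 was unchanged there. Turning the sign of a replicate pair allows 4 splits, too few for a share under 0.05. The real split gave 4 higher (1 of 4 splits as large, highest other 0), 0 lower (4 of 4), and 793 and 662 at unadjusted p (highest other 375). Signal over background limits HAS2, PTGS2 and LHCGR, which lay near the negative controls.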

Other observations

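Gene families defined by their symbols were looked at after the values were seen, so their p-values are descriptive. Of 12 families, the proteasome subunits (38 genes) had a median log2 ratio of -0.29, with 14 members lower and 2 higher at unadjusted p under 0.05. By camera the adjusted p was 6.56e-04, and 0.490 with an estimated correlation. The replicate medians were -0.23, -0.39 and -0.21, and the slide medians -0.17 and -0.34. PSMB5 lay at -1.03 ± 0.39 and PSMA5 at -0.77 ± 0.40, while PSMC1 lay at 1.08 ± 0.57. Mitochondrial ribosomal proteins, the family of MRPL57, had a median of -0.08 over 76 genes, with 7 higher and 9 lower. Subunits of mitochondrial complex I (37 genes) had a median of -0.05, with 5 higher and 9 lower and slide medians of -0.32 and 0.16, and NDUFB7 (1.06 ± 0.72) and NDUFA3 (0.76 ± 0.43) lay above 0. The growth arrest genes GADD45A (1.50 ± 0.51) and GADD45G (0.98 ± 0.24) and the AP-1 subunit FOSL1 (1.81 ± 1.21) were higher on 6 of 6 arrays, with adjusted p of 0.0829, 0.0833 and 0.110. As families, the 7 AP-1 subunits had a median of 1.23 (5 higher, 1 lower) and the 3 GADD45 genes 0.98 (2 higher, 0 lower). By camera each of these 2 families had an adjusted p of 1.95e-04, and 0.490 with an estimated correlation.

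The comparison of dye with treatment counts, the correlation of own numbers, the spike-in test, the other probes and handling were chosen only after the result was seen, and the explanations tested on single slides and by intensity were reworded then. Arrays of the 2 slides correlated weakly after turning. In the fit with the replicate block, 2122 probes passed for dye against 768 for treatment. That fit compares dye within replicates but treatment between them, so the 2 counts differ in precision. The SD over probes of the mean effect was 0.279 for dye and 0.264 for treatment. The counts go with a dye effect common to all arrays but do not show it to be larger than the treatment effect. A second slide that had not been dye-swapped stays open by this test. Own numbers correlated 0.198 more than other numbers, with an SE of 0.133. They correlated at 0.08, 0.26 and -0.13 for replicates 1, 2 and 3, against a mean of -0.13 for other numbers. That SE takes correlations that share arrays as independent, so the test cannot decide. The 4 probes that passed were higher on 6 of 6 arrays after turning, but they were picked by their turned ratios. A dye bias of all RNA that differs between slides stays open: over single spike-in spots, the difference between slides, divided by 2, had an SD of 0.0986 against 0.449 for the treatment effect over gene probes of the same intensity range, which lies between the bounds set for it. Its mean per replicate was 0.27, 0.78 and -0.01 over medians of the spike-in sequences. A bias of cell transcripts alone that differs between slides does not cancel in the average and cannot be told apart from the treatment.

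The lower ratio of cholesterol biosynthesis genes was weighed against technical explanations. Against dye bias on 1 slide only, the list was lower on each slide, with a higher unadjusted camera p of 0.0144. That p rests on the preset correlation of 0.01, whereas the estimated correlation of the list was 0.155. On the slide with cetrorelix in Cy5 alone, the camera adjusted p was 0.0830. The shared direction therefore argues against this explanation, but the camera p does not exclude it. A bias of these transcripts that reversed between the slides would lower the list on both slides, and no value tests it. A trend with intensity is argued against, because the median was -0.14 after subtracting genes of like intensity, from -0.19, with an adjusted p of 0.0236. Before that subtraction the adjusted p was 0.806 with an estimated correlation. Bias of single probes stays open: the 21 other probes of the members had a median of -0.16 but only 12 lay below 0. The 4 splits are too few to judge chance (real camera p 4.86e-04, 1 of 4 splits as small, smallest other 0.00641). An effect of LH suppression on these genes stays open and cannot be told apart from other effects of cetrorelix.

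Of 24 immediate early genes, 8 were higher and 3 lower at unadjusted p under 0.05, and the list did not pass. Handling of the cells, which could induce the whole class, stays open: of 12 genes looked at, 7 were above 0 at unadjusted p under 0.05 and 2, FOS and DUSP1, were below. FOS had a second probe at 0.02, and DUSP1 was 0.16, -1.52 and -1.74 in the 3 replicates. Dye bias on 1 slide only stays open: the list's mean was above 0 on each slide (0.21 and 0.13), with a camera p of 0.248 on the slide with cetrorelix in Cy3. A response to LH suppression remains among the open explanations and was not tested separately.

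Over 2964 genes with several probes, the 2 brightest probes correlated at r = 0.312 across genes and had the same sign in 58.0%.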
